A study of Homo sapiens with 6 samples.

How the data were processed

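Single cells of 6 libraries were analysed, from the peripheral zone and from the transition zone with urethra of the prostates of 3 organ donors, 3 libraries per zone. Per the labels the tissue was digested for 4 hours with 5 mg/mL collagenase, viable cells were sorted by flow cytometry, and 17400 cells per library were loaded on a droplet 3' assay (v2 chemistry). The labels name NextSeq and/or NovaSeq sequencers in 1 statement shared by the 6 libraries, so the sequencer of a given library is not known. The deposited matrices hold counts, raw UMI counts per gene and cell barcode, for barcodes called as cells by Cell Ranger 3.1.0 on GRCh38 per the submitters' processing notes. The release of the gene annotation is not given in the sources used here.

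Each library lists 33538 genes, of which 33456 were found by identifier in GENCODE release 29, the source of the GRCh38 coordinates given. In that annotation 2915 genes have an exon overlapping another gene on the same strand. Genes on the Y chromosome, XIST and TSIX (102 genes) were left out of every test. The 24 symbols shared by several identifiers were kept apart by identifier. The peripheral libraries of donors 1, 2 and 3 held 9499, 7881 and 7891 barcodes with 65854320, 35756956 and 46910249 UMIs, and the transition libraries 6587, 7212 and 7885 barcodes with 49751703, 41539274 and 48870941 UMIs.

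Barcodes with at least 500 genes and at most 15% mitochondrial UMIs were kept. Doublets were scored per library with Scrublet in scanpy 1.11.5 (doublet rate 0.06), and the highest scores were removed at 0.8% per 1000 barcodes. Peripheral libraries then held 8178, 6819 and 5345 cells with medians of 4985.5, 4129 and 6443 UMIs, and transition libraries 5800, 6089 and 5690 cells with medians of 6014, 5202 and 6629.5 UMIs. Counts were scaled per cell and logged, 2000 variable genes were ranked within libraries, and 30 principal components and 20 nearest neighbours gave a shared-neighbour graph for Leiden clustering at resolution 1.5 with seed 1 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, with plots from matplotlib 3.10.9). Donors were not aligned, so several clusters hold mostly 1 donor.

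Clusters were scored on marker lists of 17 cell classes fixed before the data were examined. A cluster took the best-scoring name when at least 3 of that class's markers reached 50 CPM and its 10 leading genes held more markers of that class than of any other. Otherwise it stayed unnamed. The names are therefore marker-based, and the classes are called basal-like and so on. Of 32 clusters 4 stayed unnamed.

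The share of each class was compared between zones with the exact two-sided permutation test over 20 assignments, whose smallest p is 0.1, beside an exact sign-flip test over donor pairs (smallest p 0.25) and an edgeR quasi-likelihood test on cell numbers. For gene expression, UMI counts were summed per library and class where a library had at least 20 cells of the class. Genes were filtered with filterByExpr, scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (robust, Benjamini-Hochberg adjusted per class, called at an adjusted p under 0.05). Folds are edgeR log2 fold changes, with the SE taken from the F statistic. Smooth-muscle-like cells were too few in the libraries of donors 2 and 3 to be tested. DESeq2 1.42.0 (Wald test) was run beside it.

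The label titles of both zones share a donor code, so each donor gives 1 library pair. The pairing was checked on the class profiles as deviations from their zone's mean: the correlation within a donor's own pair was 0.264 to 0.847 and above the highest other correlation (at most 0.249) in each class and donor. edgeR was therefore also run with donor as a block, which was planned as an alternative. Its values are called those of the donor-pair fit and are given beside the unpaired counts and for the genes and lists named from it.

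Named genes follow a rule fixed before the data were examined: per class, among called genes that go the same way in all 3 donor pairs, the 6 with the highest fold in each direction, given that the gene's level in that class is at least 0.25 of its level in the class where it is highest. This last condition, the free-RNA guard, keeps out transcripts of other cells. HLA, immunoglobulin, T cell receptor, mitochondrial and ribosomal protein genes, genes with common germline copy number differences and unnamed clones were not eligible. The same rule was applied to the donor-pair fit after its values were seen, with a mean of at least 10 CPM in the higher zone and no overlapping exons. Genes both class-wide and even, as defined below, were left out there, while class-wide genes of uneven level were not. In addition 13 genes were fixed in advance, of which 12 are given (KRT13, KRT4, LY6D, PSCA, SCGB1A1, SCGB3A1, PIGR, LTF, KLK3, MSMB, ACPP and KRT5). The other 1 and some genes named by these rules are not reported here. A gene counted as class-wide when at least 5 classes tested it, its log2 difference had the same sign in each of them and its median size was at least 1, and as even when its level differed by at most 4 times between classes.

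Gene lists fixed before the data were examined covered androgen response and secretion, immediate early and heat shock genes, interferon response, NF-kB and inflammatory cytokines, mucosal defence, squamous and urothelial genes, collagen and matrix, contractile genes, metallothionein and zinc transport, WNT, BMP, FGF and retinoid signals, patterning transcription factors, citrate and polyamine metabolism, and mitochondrial transcripts. Lists with at least 5 tested genes were tested with camera (limma 3.58.1, log2 CPM with prior count 2, preset correlation 0.01), adjusted over all lists and classes, and with an estimated correlation and fry beside it.

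Precision was tested on simulated data: 200 genes were changed in each of 3 runs per class. Between unpaired libraries edgeR recovered 0.345% of 2-fold and 14.7% of 4-fold changes in basal-like cells, 0.346% and 49.4% in club-like cells, and 0% and 22.8% in hillock-like cells. With donor pairs it recovered 73.7% and 96.1%, 47.0% and 95.3%, and 50.0% and 96.8%. False calls were 2.33% to 12.8% of calls over the 9 classes and both fits. A raised list of 20 genes gave a camera p of 3.86e-12 and an unchanged list 0.634. The unpaired fit thus finds few changes of 2-fold at this number of libraries.

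Alternatives were stricter (1000 genes, 10% mitochondrial) and looser filters (200 genes, no mitochondrial limit), no or stronger doublet removal (1.6%), Leiden resolutions of 0.8 and 3, gene values centred per donor before clustering, cells thinned to 1500 UMIs, the free-RNA guard applied before the adjustment, RLE size factors, no filter on low counts, at least 50 cells per library, donor as a block, and each library and each donor left out. Leaving out genes with overlapping exons and carrying the donor block through the other settings were added after the data were seen.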

Results

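Single cells were profiled from adult human prostates of organ donors, with 2 parts of the gland taken from each of 3 donors. The peripheral zone is the outer glandular part of the prostate, and the transition zone surrounds the upper urethra, which was collected with it. Each zone was represented by 3 libraries, 1 per donor, of viable cells sorted by flow cytometry and counted with a droplet 3' assay that tags each RNA molecule with a unique molecular identifier (UMI). The 6 deposited matrices held 46955 barcodes and 288683443 UMIs, between 35756956 and 65854320 UMIs per library. After filtering, 37921 cells remained, 5345 to 8178 per library, with a median of 4129 to 6629.5 UMIs per cell. Of the barcodes of donor 3, 26.4% in the peripheral and 21.4% in the transition library lay above the limit on mitochondrial UMIs, against 1.71% to 7.61% in the other 4 libraries. All differences below are transition minus peripheral, n = 3 libraries per zone.

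Most cells were epithelial. Basal-like cells, which carried KRT5, KRT14, KRT15 and DST, numbered 20039. Hillock-like cells, squamous-type epithelium led by KRT13, LYPD3 and LY6D, numbered 4557. Club-like cells, secretory epithelium led by SCGB3A1, PIGR, LCN2 and LTF, numbered 2869, and luminal-like cells, led by KLK3, MSMB and ACPP, numbered 2147. Outside the epithelium there were 2192 endothelial-like, 1644 fibroblast-like, 928 pericyte-like, 397 myeloid-like, 234 mast-like and 225 smooth-muscle-like cells. A further 2689 cells stayed unnamed: cluster 9, led by the immediate early genes EGR1 and JUN, cluster 23 with lymphocyte genes such as IL7R and JCHAIN, cluster 25 with the mural genes RGS5 and MYH11, and cluster 30 with both S100B and CHGA.

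The first comparison asked how the cell classes were shared out between the zones. Hillock-like cells made up 5.69% ± 4.68 (SD, n = 3) of peripheral and 19.5% ± 2.25 (SD, n = 3) of transition cells, a difference of 13.8 points, and were more frequent in the transition library of 3 of 3 donors. Among epithelial cells alone the hillock-like share was 6.62% ± 4.85 in the peripheral and 26.5% ± 1.90 in the transition libraries. Basal-like cells went the other way, with 61.7% ± 11.9 of peripheral and 43.8% ± 19.6 of transition cells, lower in the transition library of 3 of 3 donors. Luminal-like cells were also lower in 3 of 3 donors, at 7.61% ± 5.55 and 3.29% ± 2.80. Fibroblast-like cells (2.44% ± 2.96 and 6.15% ± 5.99) and endothelial-like cells (4.39% ± 4.37 and 6.98% ± 5.27) were higher in the transition library of 3 of 3 donors.

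For the hillock-like share the exact two-sided permutation test gave p = 0.1, the smallest value that the 20 assignments of 3 against 3 libraries allow, so no share could pass 0.05 by this test. The same exact test gave p = 0.3 for basal-like and luminal-like cells and 0.5 for fibroblast-like and endothelial-like cells. This exact permutation test gave p = 0.8 for club-like cells (6.63% ± 5.31 and 7.80% ± 6.24) and 0.7 for pericyte-like (1.93% and 2.85%) and mast-like cells (0.498% and 0.777%). For smooth-muscle-like cells it gave 0.5 (0.381% and 0.757%) and for myeloid-like cells 1 (1.09% and 1.11%). edgeR's quasi-likelihood test on cell numbers called 0 of the 10 classes, and 0 of them had an unadjusted p under 0.05. Its log2 ratio for hillock-like cells was 1.78 ± 1.15 (SE, adjusted p = 0.873), and 2.14 ± 0.72 with donor as a block (edgeR adjusted p = 0.0777). Without peripheral replicate 1 edgeR called 1 class, smooth-muscle-like cells, at a log2 ratio of 6.15. S100P, 1 of the hillock markers, was itself higher in transition libraries in other cell classes, and the sort on viability and the 4 hour digestion also bear on all of these shares. Squamous urothelial cells share hillock markers and the urethra was collected with the transition zone, so hillock-like cells of ducts and of the urethra were not told apart.

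**Figure D1:**
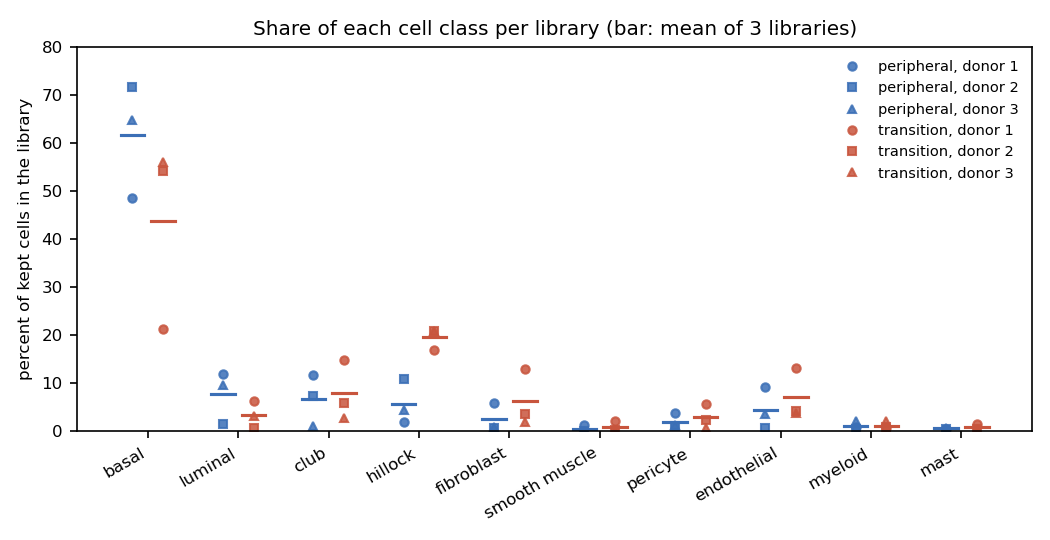
Percent of kept cells in each named class, 1 point per library, with marker shape for the donor and a bar for the mean of the 3 libraries of each zone. All 3 transition libraries lie above all 3 peripheral libraries for hillock-like cells (means 19.5% and 5.69%), while the other classes overlap between the zones.

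The second comparison asked which genes differed between the zones within 1 cell class, from UMI counts summed per library and class. In club-like cells 51 of 9638 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 38 higher and 13 lower in transition. LCN2, which encodes an antibacterial siderophore-binding protein, stood at 619 ± 187 CPM (UMI counts scaled to a common library total, SD, n = 3) in peripheral and 12241 ± 5086 CPM in transition club-like cells, a log2 difference of 4.45 ± 0.46 (SE, edgeR adjusted p = 0.00804). SRD5A2, the steroid 5-alpha-reductase that makes dihydrotestosterone from testosterone, had no UMI in any peripheral library and 135 UMIs (11.5 CPM over the summed cells) in the transition libraries. It was at least 42.6-fold higher against a floor of 3 counts over the summed peripheral cells (edgeR adjusted p = 0.0221). The naming rule required the same direction in all 3 donors. Also higher were CRISP3, a secreted cysteine-rich protein (5.76 ± 0.84, adjusted p = 0.0200 by edgeR), and SPRR1B, a cornified envelope precursor (5.53 ± 0.77, 0.0164). The same held for SNCG, gamma-synuclein (5.28 ± 0.59, edgeR adjusted p = 0.00804), and TOR4A, a torsin family member (4.83 ± 0.74, 0.0200). BPIFB2, a member of the lipid-binding BPI fold family, was lower at -3.73 ± 0.68 (edgeR adjusted p = 0.0484, 26.9 ± 23.2 and 1.94 ± 1.35 CPM). The rule also named CDK2AP1 (-5.68 ± 0.75, edgeR adjusted p = 0.0140), SNHG25 (-4.60 ± 0.46, 0.00804), EEF1G (-4.59 ± 0.55, 0.00804), EIF4EBP3 (-3.67 ± 0.59, 0.0240) and GABARAP (-3.32 ± 0.47, 0.0164). These 5 genes were lower in other classes too. In all 716 genes had an unadjusted edgeR p under 0.05.

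In GRCh38 LCN2 (ENSG00000148346) lies at chromosome 9, 128149071 to 128153455 and SRD5A2 (ENSG00000277893) at chromosome 2, 31522480 to 31581067. CRISP3 (ENSG00000096006) lies at chromosome 6, 49727384 to 49744437, SPRR1B (ENSG00000169469) at chromosome 1, 153031202 to 153032900, and SNCG (ENSG00000173267) at chromosome 10, 86958618 to 86963260. TOR4A (ENSG00000198113) lies at chromosome 9, 137277749 to 137282641 and BPIFB2 (ENSG00000078898) at chromosome 20, 33007600 to 33023709. SPRR1B shares sequence with its neighbour SPRR1A and is uncertain to that extent. The clusters of club-like cells were shared unevenly between the zones. Cluster 20, led by SCGB3A1, PIGR, LCN2, BPIFB1, NTS and PSCA, held 588, 140 and 114 cells of the transition libraries of donors 1, 2 and 3 and 6, 3 and 6 of their peripheral libraries. Cluster 12 held 908 peripheral and 266 transition cells of donor 1, and cluster 22 held 485 peripheral and 206 transition cells of donor 2. Any gene or list difference in club-like cells can therefore depend on which clusters make up the class in each zone. Whether cells of the same cluster differed between the zones was not tested. This bears most plainly on the leading genes of cluster 20. Of the fixed genes among them, SCGB3A1 stood at 482 ± 311 and 8395 ± 5812 CPM, PIGR at 130 ± 190 and 1587 ± 1282 CPM, and PSCA at 236 ± 184 and 1738 ± 785 CPM. PSCA was not called between unpaired libraries (edgeR adjusted p = 0.0991) and was called in the donor-pair fit (3.18 ± 0.25, edgeR adjusted p = 4.33e-07). SCGB1A1 stood at 456 ± 324 and 1802 ± 2500 CPM, and at a log2 difference of -0.11 without transition replicate 3 against 2.02 with all libraries. LTF stood at 136 ± 119 and 515 ± 231 CPM.

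With donor as a block edgeR called 767 genes in club-like cells, 446 higher and 321 lower in transition, and 50 of the 51 genes above were among them. Beyond SRD5A2, CRISP3, SPRR1B and SNCG, the genes named from this donor-pair fit, in this and every class by a rule written after the values were seen, were NTS, the precursor of neurotensin (10.61 ± 0.68), and DUOXA2, the maturation factor of the oxidase DUOX2 (6.41 ± 0.55). With libraries or donors left out the unpaired log2 difference of NTS ran from 5.86 to 12.32, so the size of its fold is uncertain. Lower in transition were SCGB1D2, a secretoglobin (-3.54 ± 0.33), BPIFB2 (-3.51 ± 0.35), the transcription factor SIM2 (-3.45 ± 0.62), CLEC3A (-3.20 ± 0.55), the receptor TNFRSF19 (-3.13 ± 0.49) and GLYATL2 (-2.68 ± 0.41). Over these genes donor-pair edgeR adjusted p lay between 1.92e-07 and 0.00895, and the rule required the same direction in 3 of 3 donors. DESeq2 called 181 genes between unpaired libraries. The unpaired edgeR count was 15 without peripheral replicate 3, 26 without peripheral replicate 2 and 98 without peripheral replicate 1. It was 0 without donor 3, 2 without donor 2 and 137 without donor 1. It was 11 when cells were thinned to 1500 UMIs and 33 when genes with overlapping exons were left out.

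Of the 13 fixed gene lists 5 differed as sets in club-like cells by camera with a preset correlation, the immediate early list among them given further on. Of the mucosal defence list 20 of 21 members were higher in transition, 5 of them called over all genes and 9 adjusted over the list alone (camera adjusted p = 3.86e-17, and adjusted p = 0.291 with an estimated correlation). SCGB1A1, SCGB3A1, LCN2, LTF, PIGR, WFDC2, CP, MMP7, OLFM4, BPIFB1, CHI3L1 and RARRES1 of this list are also the club markers that named the class. CP, ceruloplasmin, rose from 26.6 to 140 CPM (2.39 ± 0.42, edgeR adjusted p = 0.0422) and CXCL17 from 328 to 887 CPM (1.51 ± 0.27, edgeR adjusted p = 0.0470). Androgen response and secretion genes, with luminal markers such as KLK3, KLK4, MSMB and FOLH1 among them, were lower in 23 of 25 members with a median of -0.82 (camera adjusted p = 3.25e-06, and adjusted p = 0.303 with an estimated correlation). None of them was called over all genes, and 1 was higher and 5 were lower when adjusted over the list alone. The donor-pair fit called 1 of them higher and 9 lower over all genes. KLK3 and MSMB stood in club-like cells at 0.0643 and 0.0800 of their luminal-like levels. KLK3 stood at 736 and 266 CPM there, at 38.2 and 12.7 CPM in basal-like and 44.9 and 18.4 CPM in endothelial-like cells. In fibroblast-like cells it stood at 37.5 and 56.3 CPM, and in mast-like cells at 325 and 23.8 CPM. Peripheral MSMB stood at 2536 CPM in club-like and 2862 CPM in mast-like cells, mostly from mast-like replicate 1 (7747 CPM). Free RNA and doublets were therefore not told apart from expression by club-like cells. KLK4 stood at 75.7 and 18.7 CPM, and SORD, sorbitol dehydrogenase, at 31.1 and 110 CPM against the list's direction, both called in the donor-pair fit alone (edgeR adjusted p = 5.05e-05 and 0.0357). The squamous and urothelial list was higher in 14 of 17 members, 2 called over all genes and 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 6.81e-06, and adjusted p = 0.313 with an estimated correlation), with S100P rising from 327 to 3239 CPM (3.45 ± 0.41, edgeR adjusted p = 0.00804). The interferon list was higher in 9 of 14 members with 2 called over all genes and 2 adjusted over the list alone (camera adjusted p = 0.00417, and adjusted p = 0.505 with an estimated correlation): OAS1 rose from 8.05 to 49.9 CPM (2.61 ± 0.37, edgeR adjusted p = 0.0164) and IFI27 from 1.70 to 67.3 CPM (4.75 ± 0.56, edgeR adjusted p = 0.00804). IFI27 is a leading gene of endothelial-like cells, and its level in club-like cells was 0.0297 of that in its highest class.

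In hillock-like cells the keratin KRT13 stood at 2106 ± 1344 and 2292 ± 1110 CPM, KRT4 at 32.6 ± 24.96 and 37.5 ± 21.4 CPM and LY6D at 113 ± 123 and 107 ± 65.7 CPM in peripheral and transition libraries, differences smaller than the spread between libraries. KRT5 stood at 720 and 360 CPM and was lower in the donor-pair fit (edgeR adjusted p = 0.0178). Between unpaired libraries edgeR called 5 of 12072 genes, each lower in transition: CDK2AP1, EEF1G, GABARAP, EIF4EBP3 and SNHG25. With donor as a block it called 307 genes, 163 higher and 144 lower. FABP4, a fatty acid-binding protein, stood at 0.124 and 37.4 CPM (7.29 ± 0.63), the annexin ANXA10 at 0.0618 and 12.2 CPM (6.58 ± 0.63), SPOCD1 at 2.92 and 36.6 CPM (3.53 ± 0.45) and the trypsinogen PRSS3 at 3.52 and 32.3 CPM (3.49 ± 0.29). The peripheral levels of FABP4 and ANXA10 rest on very few UMIs, so the size of their folds is uncertain. With libraries or donors left out their unpaired log2 differences ran from 6.88 to 11.71 and from 5.53 to 10.03. The aldo-keto reductases AKR1C3 (3.30 and 58.8 CPM, 4.34 ± 0.57) and AKR1C1 (35.5 and 351 CPM, 3.47 ± 0.21), enzymes that reduce steroid ketones, were higher as well. Lower in transition were SIM2 (-2.56 ± 0.47), C5orf66-AS1 (-1.99 ± 0.30), the ammonium transporter RHCG (183 and 48.3 CPM, -1.76 ± 0.18), the folate receptor FOLR1 (-1.75 ± 0.30) and CLIC3 (-1.58 ± 0.24). Each of these 11 went the same way in 3 of 3 donors, as the rule required, with donor-pair edgeR adjusted p between 1.09e-07 and 0.0278.

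DESeq2 called 87 genes in hillock-like cells between unpaired libraries, and 454 had an unadjusted edgeR p under 0.05. edgeR called 3 without transition replicate 1 and 0 without any other single library. The donor-pair count moved with the clustering, from 183 at Leiden resolution 0.8 to 1075 at resolution 3, and was 142 with thinned cells and 199 without donor 2. The hillock-like cells of donor 1 lay mostly in cluster 14 (136 peripheral and 971 transition cells) and those of donor 3 in cluster 8 (226 and 1158), in both zones. Those of donor 2 lay mostly in cluster 16 in the peripheral (687 and 286 transition cells) and in cluster 17 in the transition library (43 and 887). RHCG is a leading gene of cluster 16. AKR1C1 and AKR1C3 are closely related members of 1 family, as are PRSS3 and the other trypsinogens, so their counts are uncertain between copies. Without peripheral replicate 1 KRT13 stood at -0.21 instead of 0.18, without donor 1 LY6D stood at -0.73 instead of 0.12 and without peripheral replicate 2 KRT4 stood at -0.11 instead of 0.34.

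Between unpaired libraries 3 lists differed as sets in hillock-like cells, and the donor-pair fit added the immediate early list (lower, camera adjusted p = 0.0106, and adjusted p = 0.637 with an estimated correlation). Squamous and urothelial genes were higher in 15 of 22 members, 0 called over all genes and 2 adjusted over the list alone (camera adjusted p = 0.00999, and adjusted p = 0.505 with an estimated correlation), where S100P stood at 687 and 2992 CPM and the water channel AQP3 at 972 and 1570 CPM. Both are among the markers that named the hillock-like class, as are KRT13, KRT4, LYPD3, LY6D, SERPINB3, SERPINB4, CSTA, UPK1A, UPK2 and UPK3A of this list. Mucosal defence genes were higher in 15 of 21 members, 0 called over all genes, 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0108, and adjusted p = 0.505 with an estimated correlation). PIGR, the receptor that carries IgA across epithelia, stood at 2.05 and 75.5 CPM, and the defensin DEFB1 at 731 and 252 CPM against the list's direction. Both were called in the donor-pair fit alone (5.20 ± 0.31 and -1.45 ± 0.20, edgeR adjusted p = 1.09e-07 and 0.000762), PIGR at 0.0476 of its level in its highest class. Metallothionein and zinc transport genes were lower in 11 of 14 members, 0 called over all genes and 2 adjusted over the list alone (camera adjusted p = 0.0102, and adjusted p = 0.313 with an estimated correlation), with MT2A at 636 and 256 CPM (donor-pair edgeR adjusted p = 0.00105). The metallothionein MT1G is a leading gene of luminal-like clusters 13 and 18, so free RNA was not told apart from expression for this list.

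In basal-like cells the keratin KRT5 stood at 895 ± 104 and 859 ± 273 CPM. Its log2 difference was -0.07, and 0.0797 without transition replicate 3. Of 14441 genes edgeR called 2 between unpaired libraries, GABARAP (66.8 and 4.20 CPM, -3.99 ± 0.24, adjusted p = 0.00618) and SNHG25 (32.0 and 2.07 CPM, -3.96 ± 0.35, adjusted p = 0.0431), both of which moved in other classes too. The donor-pair fit called 841 genes, 379 higher and 462 lower. Higher in transition were HSD17B13, a lipid droplet protein of the hydroxysteroid dehydrogenase family (1.99 ± 0.18), the nuclear receptor PPARG (17.02 and 45.2 CPM, 1.42 ± 0.28), the chemokine CCL20 (147 and 481 CPM, 1.42 ± 0.27), MTHFD1L, a mitochondrial folate enzyme (1.32 ± 0.26), MDFI (1.22 ± 0.13) and the potassium channel KCNK6 (1.13 ± 0.13). Lower were thymidine kinase TK1 (-1.85 ± 0.27), SIM2 (-1.80 ± 0.23), EIF5AL1 (-1.63 ± 0.20), CAMK2B (-1.61 ± 0.26), ARC (-1.29 ± 0.20) and the androgen-regulated transcription factor ZBTB16 (53.5 and 25.9 CPM, -1.16 ± 0.19). Their donor-pair edgeR adjusted p lay between 1.66e-05 and 0.0360, and each went the same way in 3 of 3 donors, as the rule required.

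EIF5AL1 is an expressed copy of EIF5A and is uncertain. The clusters of basal-like cells were shared unevenly between the zones too. Cluster 11, with CCL20 among its leading genes, held 103 peripheral and 1121 transition cells of donor 2, in whose transition library CCL20 stood at 983 CPM against 291 and 169 in the other two. In donor 3 cluster 2 held 813 peripheral and 1845 transition cells and cluster 4 held 1726 and 658. Between unpaired libraries, leaving out 1 library turned 3 of these 12 genes: MTHFD1L to -0.24 without transition replicate 1, SIM2 to 0.21 without peripheral replicate 2 and EIF5AL1 to 0.21 without peripheral replicate 1. DESeq2 called 65 genes, 341 had an unadjusted edgeR p under 0.05, and edgeR called 0 genes without transition replicate 1, 2 or 3 or peripheral replicate 2, 1 without peripheral replicate 1, and 0 when genes with overlapping exons were left out. Of the 841 donor-pair calls 567 had at least 0.25 of the gene's level in its highest class.

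Between unpaired libraries 5 lists differed as sets in basal-like cells by camera, none with any member called over all genes or adjusted over the list alone. Squamous and urothelial genes were higher in 14 of 17 members (camera adjusted p = 1.43e-05, and adjusted p = 0.291 with an estimated correlation). KRT13 stood at 125 ± 36.6 and 411 ± 217 CPM in basal-like cells, 0.179 of its level in its highest class, and was called in the donor-pair fit alone (1.63 ± 0.15, edgeR adjusted p = 1.25e-05). Immediate early and heat shock genes were lower in 18 of 21 members (camera adjusted p = 0.000823, and adjusted p = 0.806 with an estimated correlation). FOS stood at 633 and 387 CPM and JUN at 901 and 473 CPM (donor-pair edgeR adjusted p = 0.00493 and 0.0148). Cluster 9, nearest to basal-like cells and led by EGR1 and JUN, stayed unnamed and was left out of this class. It held 262, 248 and 343 peripheral and 125, 198 and 231 transition cells of donors 1, 2 and 3. Whether leaving them out moved the immediate early list was not tested. Collagen and matrix genes were lower in 14 of 17 members (camera adjusted p = 0.0102, and adjusted p = 0.313 with an estimated correlation), all at low levels such as 6.70 and 4.78 CPM for COL4A1. Patterning transcription factors were lower in 16 of 22 members (camera adjusted p = 0.0191, and adjusted p = 0.683 with an estimated correlation). MEIS2 stood at 73.2 and 39.8 CPM and SOX9 at 49.0 and 29.1 CPM (donor-pair edgeR adjusted p = 0.00421 and 0.00472), while PAX8, also a seminal vesicle marker, stood at 0.583 and 2.69 CPM. Androgen response and secretion genes were lower in 17 of 24 members (camera adjusted p = 0.0231, and adjusted p = 0.505 with an estimated correlation), with MSMB at 196 and 34.7 CPM, 0.00618 of its luminal-like level. In endothelial-like cells MSMB stood at 244 and 35.3 CPM. KLK3 stood at 38.2 and 12.7 CPM in basal-like and 44.9 and 18.4 CPM in endothelial-like cells. Free RNA was therefore not told apart from expression by basal-like cells. In the donor-pair fit the list members called over all genes were 6 higher and 1 lower for the squamous list, 0 and 11 for the immediate early list, 1 and 4 for collagen, 1 and 4 for patterning and 0 and 5 for the androgen list. That fit also called the mucosal defence list as higher (camera adjusted p = 0.0383, and adjusted p = 0.637 with an estimated correlation).

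In luminal-like cells KLK3, prostate-specific antigen, stood at 11436 ± 2911 and 10586 ± 1218 CPM, MSMB at 31703 ± 22523 and 24896 ± 9484 CPM and ACPP, prostatic acid phosphatase, at 4059 ± 2119 and 3969 ± 1919 CPM, each difference smaller than the spread between libraries. The androgen response and secretion list was lower there in 18 of 25 members and was not called (camera adjusted p = 0.551). The differences of all 3 genes changed sign with 1 library left out, to 0.0604 and 0.32 for KLK3 and MSMB without peripheral replicate 3 and to 0.41 for ACPP without peripheral replicate 1. edgeR called 0 of 10457 genes between unpaired libraries, 94 had an unadjusted p under 0.05, and DESeq2 called 8. edgeR called 3 without peripheral replicate 1 and 1 without transition replicate 1. The donor-pair fit called 93 genes, 32 higher and 61 lower, 38 of them with overlapping exons, and 14 without donor 1. Higher were the protease PRSS22 (0.97 ± 0.18), the inhibitor of differentiation ID3 (271 and 501 CPM, 0.94 ± 0.14), MTRNR2L1 (0.80 ± 0.15) and NAMPT, which makes NAD precursors (0.69 ± 0.15). Lower were CFAP65 (-2.29 ± 0.31), LIPE-AS1 (-1.91 ± 0.29), the adhesion molecule CHL1 (-1.85 ± 0.30), XAB2 (54.7 and 14.4 CPM, -1.66 ± 0.21), TUBA3D (-1.52 ± 0.27) and PXDN (-1.26 ± 0.25). Their donor-pair edgeR adjusted p lay between 0.000465 and 0.0358. MTRNR2L1 belongs to a family copied from a mitochondrial ribosomal RNA, and TUBA3D has near-identical tubulin copies, so both are uncertain, and MTRNR2L1 turned to -3.28 between unpaired libraries without transition replicate 2. The squamous and urothelial list was higher in 13 of 14 members, 0 called over all genes and 0 adjusted over the list alone (camera adjusted p = 0.00285, and adjusted p = 0.370 with an estimated correlation), at low levels such as 15.2 and 36.5 CPM for KRT13 (donor-pair edgeR adjusted p = 0.00173). That is 0.0159 of the level of KRT13 in its highest class. KRT13 stood at 9.19 and 35.4 CPM in fibroblast-like and 11.5 and 44.0 CPM in pericyte-like cells, so free RNA was not told apart. The donor-pair fit called 3 members of the squamous list, and added the NF-kB list as higher (camera adjusted p = 0.0106, and adjusted p = 0.647 with an estimated correlation).

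**Figure D2:**
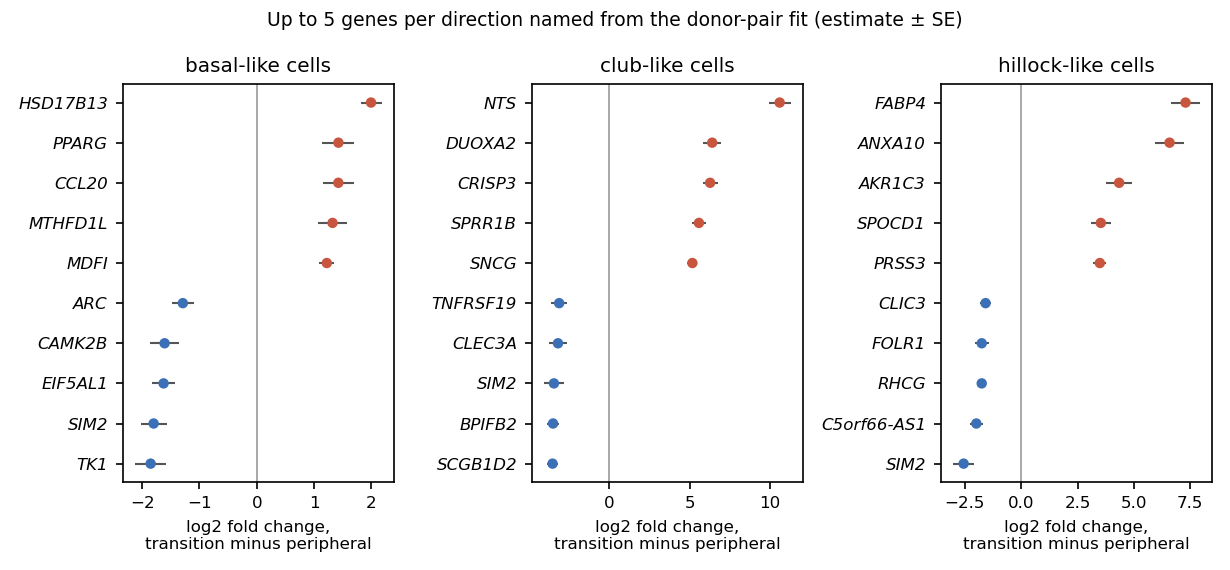
Log2 fold change, transition minus peripheral, with its SE for up to 5 genes in each direction with the largest fold among those named from the donor-pair fit in basal-like, club-like and hillock-like cells (3 donor pairs, horizontal scales differ between panels). SRD5A2 is left out because its peripheral libraries hold no UMI, and the values run from -1.85 (TK1) to 1.99 (HSD17B13) in basal-like, to 10.61 (NTS) in club-like and to 7.29 (FABP4) in hillock-like cells. The peripheral levels of FABP4 and ANXA10 in hillock-like cells rest on very few UMIs, so the size of their folds is uncertain. The size of the NTS fold in club-like cells is uncertain too.

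Genes of stromal and vascular cells were named from the donor-pair fit. Some libraries held few of these cells. Peripheral replicate 2 held 34 endothelial-like cells, peripheral replicates 2 and 3 held 40 and 47 fibroblast-like cells, and transition replicate 3 held 39 pericyte-like cells. In fibroblast-like cells MMP3, stromelysin, stood at 6.01 and 101 CPM (3.73 ± 0.35), carbonic anhydrase CA3 at 2.20 and 160 CPM (4.23 ± 0.61), the prostacyclin receptor PTGIR at 4.35 and 25.1 CPM (2.92 ± 0.46). LUCAT1 (2.99 ± 0.46), CHI3L2 (2.59 ± 0.33) and ARC (2.58 ± 0.39) were also higher in transition. Lower were ANGPTL7 (-3.90 ± 0.44), DEPP1 (-2.08 ± 0.39), tenascin C, TNC (45.8 and 10.6 CPM, -1.98 ± 0.31), the WNT antagonist SFRP4 (344 and 76.5 CPM, -1.92 ± 0.28), CNTN4 (-1.89 ± 0.39) and osteomodulin, OMD (81.9 and 23.7 CPM, -1.86 ± 0.25). In endothelial-like cells the collagenase MMP1 stood at 68.8 ± 85.6 and 810 ± 1178 CPM (3.26 ± 0.26) and MMP10 at 10.5 and 66.9 CPM (2.71 ± 0.33). EDIL3 (2.29 ± 0.36), FILIP1 (2.10 ± 0.35), the laminin LAMA4 (1.45 ± 0.30) and ST3GAL6 (1.40 ± 0.25) were also higher. CYP26B1, which degrades retinoic acid (-2.27 ± 0.37), ARC (-1.55 ± 0.34), ADIPOR2 (-1.11 ± 0.21), TIMP3, an inhibitor of metalloproteinases (712 and 390 CPM, -1.08 ± 0.20), GAS6 (-0.98 ± 0.20) and CD34 (-0.98 ± 0.22) were lower. Endothelial-like cluster 10, with MMP1 among its leading genes, held 598 peripheral and 660 transition cells of donor 1. It held 1 and 22 cells of donor 2 and 0 and 1 of donor 3. In pericyte-like cells APOE stood at 192 and 934 CPM (2.26 ± 0.21), ID4 at 344 and 1756 CPM (2.18 ± 0.20) and the chemokine CXCL2 at 393 and 1496 CPM (2.05 ± 0.18). RBFOX3 (2.88 ± 0.48) and IER3 (1.80 ± 0.26) were also higher. NOVA1 (-1.82 ± 0.33), DYNC1I2 (-1.21 ± 0.26), SPARCL1 (-0.60 ± 0.13) and MALAT1 (-0.33 ± 0.06) were lower. With libraries or donors left out the unpaired log2 differences shrank to 0.56 for MMP1, 0.19 for MMP10, 0.22 for CXCL2, 0.29 for IER3 and -0.32 for SFRP4. Adjusted p of these 33 genes in the donor-pair edgeR fit lay between 3.09e-06 and 0.0477, and each went the same way in 3 of 3 donors, as the rule required.

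Between unpaired libraries edgeR called 0 of 6482 genes in fibroblast-like, 0 of 3709 in pericyte-like and 1 of 7414 in endothelial-like cells (CDK2AP1, 35.7 and 0.623 CPM, -5.91 ± 0.63, adjusted p = 0.0421). In the same order 197, 77 and 75 genes had an unadjusted p under 0.05 and DESeq2 called 10, 3 and 6. The donor-pair counts were 77 in fibroblast-like (40 higher, 37 lower), 31 in pericyte-like (16 and 15) and 70 in endothelial-like cells (22 and 48), and leaving out 1 donor gave 105 to 372, 0 to 158 and 34 to 350. The unpaired endothelial-like call was lost without transition replicate 1, 2 or 3 or peripheral replicate 2 (0 genes each), and 3 genes were called without peripheral replicate 3. Without transition replicate 1 the count was 1 in fibroblast-like cells. In myeloid-like cells edgeR called 1 of 2160 genes (GABARAP, 169 and 9.45 CPM, -4.20 ± 0.59, adjusted p = 0.0333) and 9 with donor as a block, 35 having an unadjusted p under 0.05 and DESeq2 calling 4, with 2 called without transition replicate 1, 1 without peripheral replicate 3 and 0 without any other library. In mast-like cells edgeR called 0 of 604 genes in either fit, 9 had an unadjusted p under 0.05 and DESeq2 called 0. Between unpaired libraries 5 named genes turned when 1 library was left out: ANGPTL7 to 1.27, DEPP1 to 2.18, GAS6 to 0.0865 and CD34 to 0.0295 without peripheral replicate 3, and ST3GAL6 to -0.70 without transition replicate 1.

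Gene lists in these classes had no member called over all genes between unpaired libraries. The NF-kB and inflammatory cytokine list was higher in pericyte-like cells in 14 of 17 members, 0 adjusted over the list alone (camera adjusted p = 0.00247, and adjusted p = 0.806 with an estimated correlation), with IL6 at 442 and 1430 CPM and IL32 at 73.1 and 168 CPM (donor-pair edgeR adjusted p = 0.192 and 0.0426). Metallothionein and zinc transport genes were lower in endothelial-like cells in 9 of 11 members, 0 adjusted over the list alone (camera adjusted p = 7.99e-06, and adjusted p = 0.303 with an estimated correlation). MT2A stood there at 2995 and 1305 CPM and MT1E at 123 and 28.7 CPM (donor-pair edgeR adjusted p = 0.00117 and 6.73e-06). MT1E is also a leading gene of luminal-like cluster 18, so free RNA was not told apart from expression for it. The metallothionein list was also lower in myeloid-like cells in 5 of 6 members, 0 adjusted over the list alone (camera adjusted p = 0.0409, and adjusted p = 0.806 with an estimated correlation). Free RNA was not told apart from expression for this list in either class, since MT1G too is a leading gene of luminal-like clusters. Immediate early and heat shock genes were lower in endothelial-like (19 of 21 members, camera adjusted p = 0.00894), club-like (18 of 21, 0.0126) and fibroblast-like cells (17 of 21, 0.0191), none adjusted over the list alone, with adjusted p = 0.806, 0.683 and 0.823 with an estimated correlation. The endothelial-like immediate early list was lost and its direction turned without peripheral replicate 3 (camera adjusted p = 0.556). With 1 library left out the camera adjusted p reached 0.996 for the fibroblast-like and 0.315 for the club-like immediate early list. It reached 0.420 for the pericyte-like NF-kB, 0.568 for the myeloid-like metallothionein and 0.329 for the endothelial-like squamous list. Mitochondrial transcripts were higher in myeloid-like cells in 10 of 11 members, 0 adjusted over the list alone (camera adjusted p = 0.0191, and adjusted p = 0.509 with an estimated correlation). Epithelial lists moved here too: the squamous list was higher in endothelial-like (4 of 6 members, camera adjusted p = 0.00551) and myeloid-like cells (4 of 5, 0.000899), with 1 and 2 members higher when adjusted over the list alone, and the androgen list lower in endothelial-like cells (15 of 16, 0.000473, none over the list alone), with adjusted p = 0.505, 0.303 and 0.313 with an estimated correlation. KLK3 stood in endothelial-like cells at 44.9 and 18.4 CPM, 0.00392 of its luminal-like level.

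Across the 9 classes camera called 23 combinations of list and class, 30 with donor as a block and 0 with an estimated correlation or by fry. Of the 23, 11 were kept without peripheral replicate 3, where 14 were called in all, 15 without transition replicate 1 and 16 without peripheral replicate 1. The numbers kept were 19 without peripheral replicate 2, where 36 were called, 20 without transition replicate 2 and 21 without transition replicate 3. Beyond those named above the donor-pair fit added the metallothionein list as lower in club-like (camera adjusted p = 0.0226), the immediate early list as lower in pericyte-like (0.00483) and mitochondrial transcripts as higher in mast-like (0.0226) and pericyte-like cells (0.0246). With an estimated correlation the adjusted p of these 4 were 0.629, 0.808, 0.770 and 0.780. The contractile list (smallest camera adjusted p = 0.0969), the citrate and polyamine list (0.131) and the list of WNT, BMP, FGF and retinoid signals (0.171) were called in no class between unpaired libraries.

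A group of genes that were similarly abundant in all classes differed by similar amounts in most classes tested. CDK2AP1, a partner of the kinase CDK2, differed by -6.11 to -5.46 in basal-like, luminal-like, club-like, hillock-like, fibroblast-like and endothelial-like cells, and the elongation factor subunit EEF1G by -4.68 to -4.47 in the same classes. The transition libraries held no UMI of EEF1G in myeloid-like cells and none of GABARAP in mast-like cells. The autophagy gene GABARAP, the snoRNA host gene SNHG25, the ribosomal protein gene RPS10 and the complex I subunit NDUFA13 were also lower in transition in each class that tested them, RPS10 by -1.51 to -1.28 and by -0.92 in mast-like cells, while MTRNR2L8 was higher. In basal-like cells RPS10 stood at 1980 ± 504 and 760 ± 132 CPM, NDUFA13 at 217 ± 10.9 and 84.3 ± 17.4 CPM and MTRNR2L8 at 362 ± 220 and 831 ± 396 CPM. These 7 genes were picked as examples after their values were seen. Of the 29 genes that were similarly abundant in all classes and differed in the same direction in each class tested, at least 5, 23 were lower and 6 higher in transition. They accounted for 2 of 2 basal-like, 4 of 5 hillock-like and 6 of 51 club-like calls between unpaired libraries, and for the only endothelial-like and the only myeloid-like call. Of the donor-pair calls they were 28 of 841 in basal-like, 23 of 93 in luminal-like, 22 of 767 in club-like, 23 of 307 in hillock-like, 17 of 77 in fibroblast-like, 10 of 31 in pericyte-like, 21 of 70 in endothelial-like and 7 of 9 in myeloid-like cells. Class-wide genes whose level was not even are outside these 29. Among them are LCN2 (7 classes tested, median log2 difference 2.09), PPARG (5, 1.40) and RBFOX3 (7, 1.28). They were named above in club-like, basal-like and pericyte-like cells in that order. Each was higher in transition in every class that tested it.

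**Figure D3:**
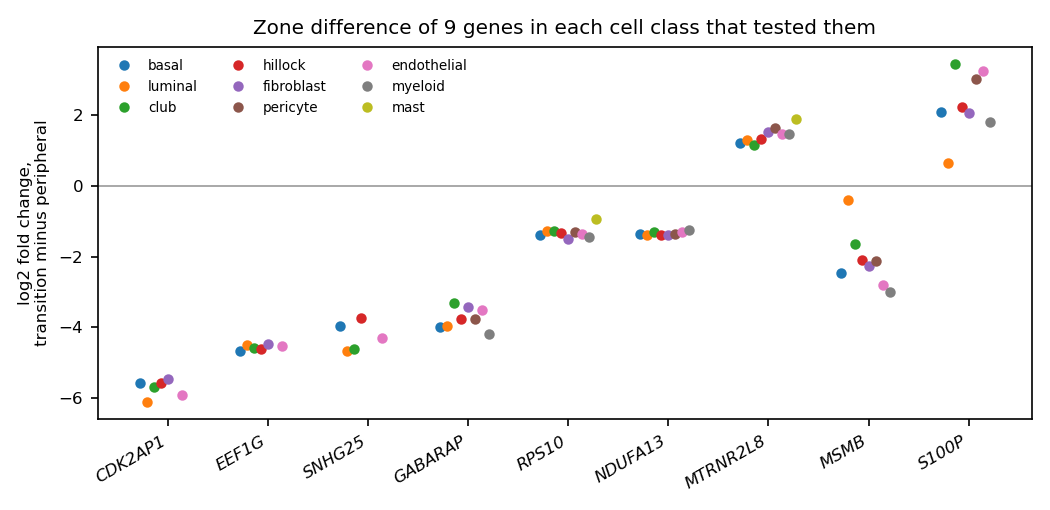
Log2 fold change, transition minus peripheral, of 9 genes in each cell class that tested them, 1 point per class. EEF1G in myeloid-like cells and GABARAP in mast-like cells are left out because the transition libraries hold no UMI of them there. CDK2AP1, EEF1G, SNHG25, GABARAP, RPS10, NDUFA13 and MTRNR2L8 lie at nearly 1 value in most classes, while the epithelial genes MSMB and S100P spread more widely, MSMB from -0.39 in luminal-like to -2.99 in myeloid-like cells.

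Exons of another gene on the same strand overlap CDK2AP1 (chromosome 12, 123260971 to 123272334, ENSG00000111328), EEF1G (chromosome 11, 62559601 to 62574086, ENSG00000254772) and GABARAP (chromosome 17, 7240014 to 7242770, ENSG00000170296). They also overlap RPS10 (chromosome 6, 34417454 to 34426125, ENSG00000124614) and NDUFA13 (chromosome 19, 19515736 to 19529054, ENSG00000186010). Counts of such genes are uncertain because a counter that leaves out reads shared by 2 genes lowers them. SNHG25 (chromosome 17, 64145970 to 64146476, ENSG00000266402) has no such overlap in the annotation used here, and MTRNR2L8 (chromosome 11, 10507887 to 10509189, ENSG00000255823) resembles the mitochondrial genome. EIF4EBP3, a repressor of translation initiation named in club-like (-3.67 ± 0.59, edgeR adjusted p = 0.0240) and hillock-like cells (-3.75 ± 0.43, edgeR adjusted p = 0.0442), lies at chromosome 5, 140547666 to 140549578 (ENSG00000243056). Its exons overlap another gene too, so its counts are uncertain in the same way.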

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

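Leaving out genes with overlapping exons and running the donor-pair fit through the other settings were tests chosen after the data were seen. The other alternatives were planned.

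The share of hillock-like cells was higher in transition libraries in each setting run, with each library and each donor left out too. No class was called by edgeR on cell numbers in any setting with all libraries, and leaving out 1 library or donor gave 0 to 1 (1 without peripheral replicate 1, smooth-muscle-like cells). The difference in mean percent of myeloid-like cells turned to -0.104, and its edgeR log2 ratio to -0.14, with the stricter filter. With libraries or donors left out, the differences in mean percent that changed sign ran from -2.32 to 3.70 for club-like, -0.280 to 0.748 for smooth-muscle-like, -0.504 to 2.00 for pericyte-like, -0.444 to 4.97 for endothelial-like, -0.407 to 0.522 for myeloid-like and -0.0909 to 0.562 for mast-like cells. The edgeR log2 ratios of cells ran from -0.62 to 0.90, -1.90 to 6.15, -0.44 to 1.39, -0.15 to 1.79, -0.67 to 0.91 and -0.27 to 1.26 in the same order. The lowest values came without transition replicate 1 for club-like, smooth-muscle-like, pericyte-like and endothelial-like cells, without transition replicate 3 for myeloid-like and without donor 1 for mast-like cells.

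The counts of genes called between unpaired libraries moved as follows. In basal-like cells (2 genes) edgeR called 4 with the stricter filter, 4 with the looser filter, 4 with more doublets removed, 5 with thinned cells, 6 with the guard before the adjustment, 6 with no filter on low counts, 0 with overlapping genes left out and 841 with donor as a block, DESeq2 called 65, and leaving out libraries or donors gave 0 to 2. In luminal-like cells (0 genes) edgeR called 1 with more doublets removed, 3 with the guard, 7 with no filter and 93 with donor as a block, DESeq2 called 8, and leaving out libraries or donors gave 0 to 3. In club-like cells (51 genes) edgeR called 100 at Leiden resolution 0.8, 11 with thinned cells, 33 with overlapping genes left out, 371 with no filter and 767 with donor as a block, DESeq2 called 181, and leaving out libraries or donors gave 0 (without donor 3) to 137 (without donor 1). In hillock-like cells (5 genes) edgeR called 3 with the looser filter, 0 with more doublets removed, 3 at Leiden resolution 3, 2 with values centred per donor, 0 with overlapping genes left out, 20 with no filter and 307 with donor as a block, DESeq2 called 87, and leaving out libraries or donors gave 0 to 3.

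In fibroblast-like cells (0 genes) edgeR called 41 with no filter and 77 with donor as a block, DESeq2 called 10, and leaving out libraries or donors gave 0 to 1. In pericyte-like cells (0 genes) the counts were 17 with no filter, 31 with donor as a block and 3 by DESeq2. In endothelial-like cells (1 gene) edgeR called 2 with no doublet removal, 0 at Leiden resolution 3, 0 with thinned cells, 2 with the guard, 0 with overlapping genes left out, 19 with no filter, 0 with at least 50 cells per library and 70 with donor as a block, DESeq2 called 6, and leaving out libraries or donors gave 0 to 3. In myeloid-like cells (1 gene) edgeR called 0 with the stricter filter, the looser filter, more doublets removed, thinned cells or overlapping genes left out, 13 with no filter, 6 with at least 50 cells per library and 9 with donor as a block, DESeq2 called 4, and leaving out libraries or donors gave 0 to 2. In mast-like cells (0 genes) edgeR called 3 with no filter. RLE size factors moved none of these counts by over 1.5 times. Fewer genes adjusted for (overlapping genes left out) and fewer libraries are part of the construction of those settings, and the cause of the other moves was not tested.

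The donor-pair counts moved less in basal-like and club-like cells than these. In luminal-like cells (93 genes) they were 142 with the looser filter, 155 with values centred per donor, 33 with thinned cells, 40 with overlapping genes left out and 14 (without donor 1) to 143 (without donor 2). In club-like cells (767) 385 were called with thinned cells. In hillock-like cells (307) the counts were 544 with the stricter filter, 709 with no doublet removal, 853 with more doublets removed, 183 at Leiden resolution 0.8, 1075 at Leiden resolution 3, 887 with values centred per donor, 142 with thinned cells and 199 (without donor 2) to 362 (without donor 3). They were 105 to 372 (without donor 3) with donors left out in fibroblast-like cells (77), 14 with thinned cells and 0 (without donor 1) to 158 (without donor 2) in pericyte-like cells (31), and 39 with thinned cells and 34 (without donor 1) to 350 (without donor 2) in endothelial-like cells (70). In myeloid-like cells (9) they were 32 with the stricter filter, 15 with thinned cells, 3 with overlapping genes left out and 0 (without donor 1) to 41 (without donor 3). In mast-like cells (0) they were 3 with the looser filter, 9 with no doublet removal, 17 with thinned cells and 0 to 3 (without donor 2). The cause was not tested.

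Of the 23 list calls 0 were kept with an estimated correlation and 0 by fry, and leaving out 1 library gave 14 to 36 calls. The immediate early list in endothelial-like cells turned without peripheral replicate 3, with camera adjusted p from 7.72e-06 to 0.556 over the libraries left out. In basal-like cells the immediate early list reached a camera adjusted p of 0.446 with 1 library left out. The mucosal defence, androgen, squamous and interferon lists in club-like cells stayed called with each library left out. Apart from the counts above, donor as a block changed no list call to its opposite and kept all 23.

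The 106 combinations of named gene and class stayed on their side of the threshold and in their direction in 2106 settings, passed it newly in 137, no longer passed it in 146 and changed sign in 42. The side was that of the unpaired fit. Genes named from the donor-pair fit alone and the fixed genes were not called there. For them, most of the combinations, staying on their side means staying uncalled. MTRNR2L1 in luminal-like cells stood at -3.12 with the stricter filter and -3.28 with at least 50 cells per library, and at -3.28 to 4.92 with libraries or donors left out. ACPP in luminal-like cells stood at 0.22 with the stricter filter, 0.0213 with more doublets removed, 0.0203 at Leiden resolution 0.8, 0.0181 with donor as a block and 0.25 with at least 50 cells, and at -0.59 to 0.41 with libraries or donors left out. KLK3 in luminal-like cells stood at 0.0363 with at least 50 cells and at -0.32 to 0.0604 with libraries or donors left out. KRT13 in hillock-like cells stood at -0.17 at Leiden resolution 0.8 and -0.21 to 0.71 with libraries or donors left out, and LY6D at -0.16 with thinned cells and -0.73 to 1.49.

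Leaving out libraries or donors alone changed the sign of MTHFD1L (-0.24 to 3.16), SIM2 (-4.23 to 0.21), EIF5AL1 (-3.44 to 0.21) and KRT5 (-0.34 to 0.0797) in basal-like cells, MSMB (-0.80 to 0.32) in luminal-like cells, SCGB1A1 (-0.11 to 2.74) in club-like cells and KRT4 (-0.11 to 1.03) in hillock-like cells. The same held for ANGPTL7 (-10.95 to 1.27) and DEPP1 (-5.35 to 2.18) in fibroblast-like cells and for ST3GAL6 (-0.70 to 3.68), GAS6 (-1.66 to 0.0865) and CD34 (-1.33 to 0.0295) in endothelial-like cells. Other named genes kept their sign but their log2 difference shrank by over 1.5 times, to the value given. They were HSD17B13 (0.95), CCL20 (0.62), TK1 (-0.50), CAMK2B (-0.92), ARC (-0.53) and ZBTB16 (-0.52) in basal-like and PRSS22 (0.51), NAMPT (0.00846), TUBA3D (-0.26) and PXDN (-0.36) in luminal-like cells. They were NTS (5.86) and LTF (1.09) in club-like and PRSS3 (1.64), SIM2 (-1.17) and RHCG (-1.20) in hillock-like cells, SFRP4 (-0.32) in fibroblast-like, and ID4 (1.27), CXCL2 (0.22), IER3 (0.29) and SPARCL1 (-0.23) in pericyte-like cells. In endothelial-like cells they were MMP1 (0.56), MMP10 (0.19), CYP26B1 (-0.72), ARC (-0.71) and TIMP3 (-0.46). SPRR1B (9.53), SIM2 (-7.18) and PIGR (6.23) in club-like, FABP4 (11.71) in hillock-like and MMP3 (5.69) in fibroblast-like cells grew by over 1.5 times. These are unpaired fits, in which a library left out leaves its donor in 1 zone alone. The cause was not tested.

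Centring per donor left too few libraries with 20 club-like cells to test that class, and at least 50 cells per library left too few for fibroblast-like and mast-like cells. Thinning to 1500 UMIs lowers the depth of each cell, and with it the depth of the summed counts.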

Other observations

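Of the tests in this part, those of overlapping gene models and of the sequencing statements for the class-wide genes, and those of the loose filter, of the epithelial denominator and of a loss of basal-like cells for hillock-like cells, were chosen only after the result was seen.

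The unnamed clusters hold cells of both zones. Cluster 9 (1407 cells), nearest to basal-like cells by its markers, was led by EGR1, JUN, EDN1, EGR2, IER2 and ATF3, and drew between 125 and 343 cells from each library. Cluster 23 (633 cells) carried immunoglobulin genes and JCHAIN beside IL7R and KLRB1, so B, plasma, T and NK cells were not parted in it. Cluster 25 (529 cells) carried RGS5 and GJA4 of pericytes beside ACTA2 and MYH11 of smooth muscle. Cluster 30 (120 cells) carried the glial gene S100B beside the neuroendocrine genes CHGA, TPH1, GRP and CALCA. Cluster 32 (49 cells), named basal-like, was led by the cell cycle genes UBE2C, TOP2A and MKI67, and 35 of its cells came from peripheral replicate 1.

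The first pattern is the set of 29 genes, CDK2AP1, EEF1G and GABARAP among them, that were similarly abundant in all classes and differed in the same direction in each class tested, at least 5. Of the 23 lower genes 60.9% have an exon overlapping another gene on the same strand, against a median of 8.70% and an upper limit of 21.7% for the middle 95% of 10000 expression-matched random sets. A counter that drops reads shared by 2 genes lowers such genes in every class, but 1 counter used alike for both zones would not by itself give a zone difference. Of the 6 higher genes 16.7% have such an exon, within the matched range of 0% to 33.3%, and 6 genes are too few to decide. Transcript length cannot be told apart: the median longest transcript of all 29 was 2240 bases, below the matched range of 2359 to 4392, but each direction lay inside its own (lower genes 2496 against 2334 to 4603, higher genes 1799.5 against 1643 to 5574). The labels give 1 sequencing statement for the 6 libraries, so a sequencing or counting difference between the libraries of the zones cannot be told apart from a zone difference. A biological zone difference in these genes stays open and was not tested.

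The second pattern is that luminal and hillock markers were counted in non-epithelial classes, such as KLK3 and MSMB in endothelial-like cells. Free RNA of epithelial cells is a candidate source: of 75 combinations of gene and class (34 genes) 61, or 81.3%, had the sign of the whole-library difference between the zones. Doublets with epithelial cells cannot be told apart from it, since removing more doublets lowered the summed level of these genes by 10.9%, from 941 to 838 CPM, against 1499 CPM with no doublet removal, a fall between those set in advance for and against them. The squamous and androgen lists in endothelial-like and myeloid-like cells were therefore not read as expression by those cells. MSMB, KLK3 and ACPP stood in basal-like cells near their endothelial-like levels, and KRT13 in luminal-like cells near its fibroblast-like level. The androgen list in basal-like and the squamous list in luminal-like cells were therefore not read so either. Whether any of these cells express such genes was not tested.

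The third pattern is the higher share of hillock-like cells in the transition libraries. The tables argue against cells lost at the filters, since with the loose filter the difference was 13.4 points, and against a shift in non-epithelial cells, since among epithelial cells it was 19.9 points. Basal-like cells fell from 75.2% to 56.7% of epithelial cells. A loss of them alone would leave the ratio of hillock-like to luminal-like cells unchanged, but its log2 rose by 3.37 ± 1.20 (SD, n = 3 donors), which argues against it. Among epithelial cells that were not basal-like the hillock-like share rose in 3 of 3 donors (6.99% and 44.6%, 55.7% and 76.1%, 29.4% and 78.4%). After each cell was thinned to 1500 UMIs the share of cells with a KRT13 UMI was higher in the transition library of 3 of 3 donors (5.64% and 18.1%, 13.3% and 32.2%, 7.65% and 25.9%). This argues against deeper cells as the source of that KRT13 difference. The classes were not named again from thinned cells, so the test does not reach the hillock-like share itself. In basal-like cells the shares with a KRT13 UMI rose too (8.15% and 21.3%, 8.23% and 23.2%, 4.82% and 14.2%). In endothelial-like cells, which should lack KRT13, the shares were 0.853% and 2.44%, 9.38% and 6.28%, and 1.71% and 7.69%, with median depths before thinning of 4063 and 5022, 3525 and 4262, and 4547.5 and 5209 UMIs, against 5104 and 6127, 4205 and 5354, and 6560 and 6717.5 UMIs in all cells. The urethra was collected with the transition zone and its squamous urothelial cells share hillock markers, so cells of the urethra stay open as a source. So do a difference in how well the dissociation released these cells and a biological zone difference, all untested.

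The 6 libraries have 10 splits of 3 against 3, too few for a share of splits under 0.05. The unpaired edgeR counts, with the highest of the other splits in second place, were 2 and 0 in basal-like, 0 and 778 in luminal-like, 51 and 1 in club-like, 5 and 0 in hillock-like, 0 and 0 in fibroblast-like, 0 and 60 in pericyte-like, 1 and 290 in endothelial-like, 1 and 4 in myeloid-like and 0 and 4 in mast-like cells. Splits calling as many genes as the real one, itself included, were 1 in basal-like, club-like and hillock-like, 3 in endothelial-like, 2 in myeloid-like and 10 in luminal-like, fibroblast-like, pericyte-like and mast-like cells. Those that called 778, 290 and 60 genes point to a structure of the samples. Of the 10 splits 4 part all 3 pairs. With donor as a block the real split called 841 genes in basal-like, 93 in luminal-like, 767 in club-like, 307 in hillock-like, 77 in fibroblast-like, 31 in pericyte-like, 70 in endothelial-like, 9 in myeloid-like and 0 in mast-like cells, against at most 0, 25, 0, 0, 0, 4, 4, 0 and 9 in the other splits that part all pairs, each of which puts a library of either zone in both of its groups.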
